A study of Mus musculus with 80 samples.

How the data were processed

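RNA was measured by sequencing in mouse ES cells, in 12 libraries of 9 groups whose tables were used here. Per the submitters' processing notes, the tools used over the series were TopHat, Bowtie 0.12.7, SAMtools and MACS 1.4.2, and the genome build was mm9. Which of them made each expression table is not given in the sources used here. The protocol of the RNA libraries, including how the RNA was selected, is not given there either. The deposited FPKM values (fragments per kilobase, scaled to mapped fragments) cover both Sall4 het and KO libraries of replicate 1, the DKO and its control, the Sall1 het and KO libraries, KO plus wild type, KO plus mutant replicate 1 and TT2, per the file headers. The deposited RPKM values (reads per kilobase, scaled to mapped reads) cover replicate 2 of Sall4 het, Sall4 KO and KO plus mutant. These units hold no read totals and whole reads could not be recovered, so depth is unknown and no interval for counting error is given. A value of 0 is reported only as listed. Sums of values ranged from 835259 in the DKO control to 7359940 in Sall4 het replicate 1, where the 10 highest entries held 79.8% of the sum, so a few genes weigh on these units.

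The tables differ in annotation. Those of Sall4 het and KO replicate 1 have 37883 entries, of which 1225 name no gene and were left out. The other FPKM tables at gene level have 23235 or 23234, those of Sall4 het and KO replicate 2 have 19049, and that of KO plus mutant replicate 2 has 20223. The TT2 table is at transcript level, and 99.3% of its 21689 gene identifiers were matched to symbols in a RefSeq table of assembly GRCm38.p6, which was used for names only. In KO plus mutant replicate 2, 18 shifted symbols were set by their Ensembl identifier. Entries with the same symbol were summed. TT2 entered no fit or ratio, and only its deposited values are given. Strain labels differ between the replicates of a group. The samples of chromatin and modified DNA were not analysed here.

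Before the data were examined, the groups, tests, alternatives, 21 gene lists and the rule for naming genes were fixed. For Sall4 het, Sall4 KO and KO plus mutant, values were scaled by the median ratio over genes at 1 or more in all libraries, a pseudocount of 1 was added and log2 taken. Genes at 1 or more in at least 2 of 6 libraries were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with terms for group and replicate number, because replicates 1 and 2 carry different units. Tests are two-sided and p-values were adjusted by Benjamini and Hochberg at 0.05 within each of 3 comparisons. All fold changes are on the log2(value + 1) scale, which understates the change of low genes. Gene lists were tested with camera at a preset correlation of 0.01 over genes measured in all 6 libraries, adjusted over 20 lists, and again with an estimated correlation and with fry.

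Pairs of single libraries were given no test. Their log2 ratios use the same scaling and pseudocount, among genes at 5 or more in at least 1 library, with 2-fold as the limit. A list's median is placed as a percentile among 10000 random lists of the same size matched on mean level, over members at 1 or more, as a description of those libraries. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. Scripts for the fit and the ratios were tested on simulated data. For 11632 genes, values were drawn independently with the residual spread of the fit on all 6 libraries. For limma a replicate shift common to all groups was added. It called 48 of 50 genes changed 8-fold between KO and het and 7 of 11256 unchanged genes. Camera ranked the 1 moved list first. Because the simulated genes were independent, this does not check the preset correlation.

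Genes were named by rule. The SALL and TET genes come first, then for each tested comparison up to 10 genes per direction past the threshold, filled by the size of the smaller of the replicate changes at a value of at least 5, and for single pairs the 10 largest ratios per direction. Up to 4 members of each list with the largest change could be named, of which the first 2 in rank order were used, a limit set after the data had been seen. The comparison of the add-back libraries with each other, the list tests without mutant libraries and the symbols set by identifier were also decided then. Some genes that the rule names are not reported here. Predicted genes, clone names, pseudogenes, microRNAs, small nucleolar RNAs and some other small RNA families were left out, but not Rnu11, Rnu12 and Rmrp, and the exclusion of clone names and of some small RNA families was also set later.

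The lists were the SALL family, cytosine methylation and oxidation, naive and core pluripotency, primed epiblast, trophoblast, primitive endoderm, primitive streak and mesoderm, neuroectoderm, germline genes, two-cell-like genes, imprinted genes, the NuRD complex, Hox genes, fibroblast feeder markers, p53 targets, LIF and STAT3 targets, WNT targets, FGF and ERK feedback, glycolysis, cholesterol synthesis and replication-dependent histones. Alternatives were pseudocounts of 0.1 and 5, other filters and levels, values as deposited, quantile normalization, 1 entry per symbol, other forms of the limma fit, and leaving out each library in turn.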

Results

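The series profiled mouse embryonic stem (ES) cells, the self-renewing cells of the early embryo, with lines labelled as lacking SALL4, SALL1 or both, which are zinc finger transcription factors of the spalt-like family. Of its 80 samples, 12 are RNA-seq libraries whose expression tables were used here. The other 68, which profile chromatin and modified DNA together with their inputs, were not analysed here. Sall4 heterozygous, Sall4 KO and Sall4 KO cells given a mutant SALL4A had 2 libraries each. The remaining 6 groups had 1 library each: Sall4 KO given wild-type SALL4A, the Sall1/Sall4 double knockout (DKO), its wild-type control, Sall1 heterozygous, Sall1 KO, and the wild-type TT2 line. Values were FPKM or RPKM, which hold no read totals, so the depth is unknown and no counting error can be given. Nothing in the labels says that same-group libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The replicates of a group also differ in strain label, unit and annotation, which the term for replicate number cannot tell apart.

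The targeted genes were read first in every library. Sall4 (chromosome 2, 168573831 to 168592701 in mm9) was not low in the libraries labelled as lacking it. Its deposited value was 196 and 64.2 in the libraries labelled Sall4 het and 358 and 218 in those labelled Sall4 KO. It was 17.6 in the wild-type control of the DKO and 109 in the library labelled DKO. The libraries labelled KO plus mutant stood at 77.4 and 161, KO plus wild type at 97.4, Sall1 het at 18.6, Sall1 KO at 17.8 and TT2 at 12.8. In limma, Sall4 differed between the libraries labelled KO and het by a log2 change of 1.27 ± 0.67 (SE, n = 2 per group), higher in both replicates, with an adjusted p of 0.693. The RNA of Sall4 therefore goes against the label in both KO libraries and in the DKO library. Which exons were deleted is not given in the sources used here. A value for the whole gene can include parts that were not deleted, so these Sall4 values check no label. Every direction below is between libraries as labelled.

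Sall1 (chromosome 8, 91551142 to 91568061 in mm9) was 2.27 in the library labelled DKO and 13.9 in its control, a log2 ratio of -2.17. It was 13.3 in the library labelled Sall1 KO and 21.8 in Sall1 het, a log2 ratio of -0.67. In the libraries labelled Sall4 het it was 27.1 and 37.8, in Sall4 KO 49.7 and 67.9, in KO plus mutant 43.9 and 28.5, in KO plus wild type 48.8 and in TT2 10.8. Sall2 lay between 0.366 in TT2 and 5.78 in the library labelled Sall1 het. Sall3 lay between 0.103 in TT2 and 3.90 in the library labelled DKO, and the table of KO plus mutant replicate 2 does not list it. Of the dioxygenases that oxidise 5-methylcytosine, Tet1 ranged from 9.56 in the library labelled DKO to 27.5 in Sall4 het replicate 1. Tet2 ranged from 3.40 in DKO to 9.88 in TT2, and Tet3 from 0.357 in the DKO control to 2.48 in Sall4 KO replicate 1. Between the libraries labelled Sall4 KO and het, log2 changes were -0.065 ± 0.31 for Tet1, 0.090 ± 0.25 for Tet2 and 0.62 ± 0.22 for Tet3 (SE, n = 2 per group), with limma adjusted p of 0.982, 0.969 and 0.559. Without Sall4 het replicate 1 the Tet1 value was 0.36 and without Sall4 KO replicate 1 it was 0.10. Without Sall4 KO replicate 1 that of Tet2 was -0.11.

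**Figure D1:**
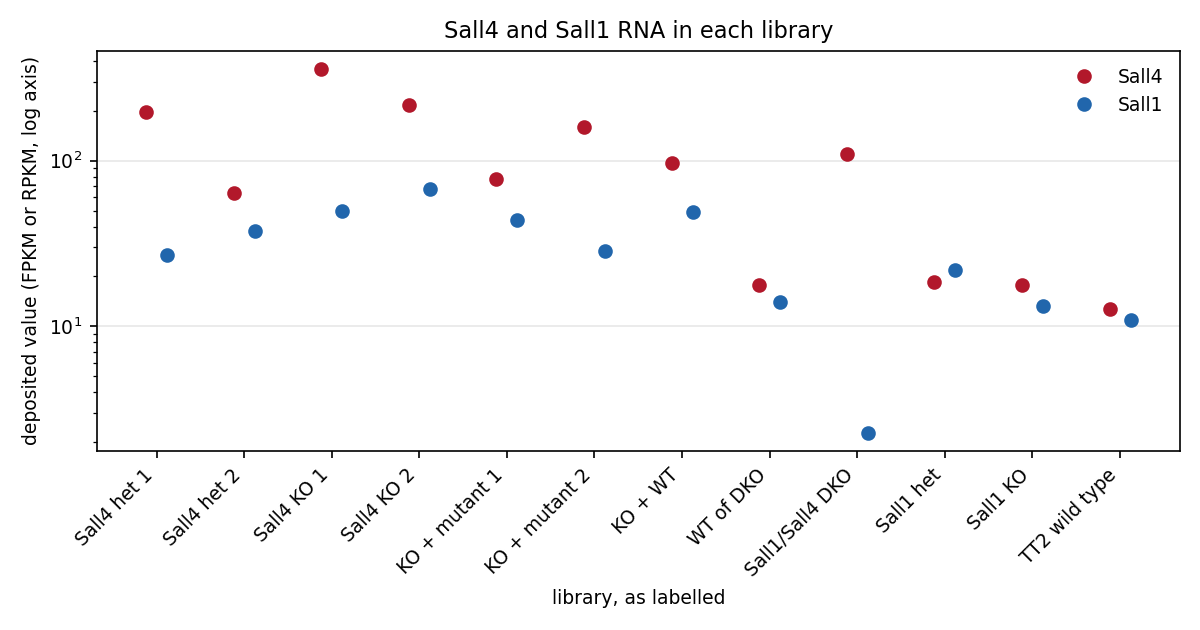
Deposited value of Sall4 and Sall1 (vertical log axis, FPKM or RPKM) in each of the 12 libraries as labelled, 1 point per library and gene. Sall4 stands at 358 and 218 in the libraries labelled Sall4 KO and at 109 in the DKO, while Sall1 stands at 2.27 in the DKO.

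Comparing the libraries labelled Sall4 KO with those labelled Sall4 het asks which RNAs differ when SALL4 is lost. Dpp4, a cell-surface peptidase, was 44.4 and 37.7 in the KO libraries against 6.88 and 4.35 in het, a log2 change of 2.64 ± 0.28 (SE, n = 2 per group). Dppa3, a germ-cell and pluripotency factor that protects 5-methylcytosine in the early embryo, was 2.11 and 3.58 against 47.7 and 183, a log2 change of -4.66 ± 0.72. In the camera test, cholesterol synthesis and germline genes were lower as lists, and primitive endoderm markers, imprinted genes and p53 targets were higher. With an estimated correlation the adjusted p was 0.537 for each, so these calls hold only in the form with a preset correlation. The forms differ in more than the correlation. For cholesterol synthesis the estimate was 0.033, yet the camera p rose from 1.54e-08 to 0.0387. With 6 libraries the estimated form has few degrees of freedom and little power. It cannot show whether the correlation alone decides the calls. Sall4 RNA itself was higher in the KO libraries, against their label.

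No single gene passed the test, so the genes here are ranked by the smaller of their replicate changes and not called. After Dpp4 the higher side held Tmem156 (2.43), Emp1 (2.33), the paternally expressed imprinted gene Peg3 (2.13), the secreted glycoprotein gene Fstl1 (2.16), Wls (2.14), which encodes the carrier of WNT ligands, Itm2a (2.07), Tmem90b (1.96), Cachd1 (2.12) and D1Pas1 (2.05), as log2 changes. On the lower side, Dppa3 was followed by the Y-linked translation factor gene Eif2s3y (-3.73), Arhgap27 (-3.40), Xlr3a (-3.54), the kinase gene Braf (-2.87), Slc4a5 (-2.67), the deubiquitinase gene Usp26 (-2.96), the metallothionein gene Mt4 (-3.28), Krtdap (-2.65) and Magohb (-2.81). Eif2s3y was 12.3 and 33.1 in the het libraries and 0.0391 and 1.39 in the KO libraries. Of 6 Y-linked genes at 1 or more in both het libraries, 4 are listed for all 5 libraries of KO and add-back cells, and those 4 were below both het values in each. Limma called 0 of 15078 genes at an adjusted p of 0.05, with 1283 at an unadjusted p under 0.05, and the smallest adjusted p was 0.237. Simulated data for 11632 genes used the residual spread of the fit on all 6 libraries. There the same fit called 4 of 50 genes changed 2-fold and 39 of 50 changed 4-fold. The simulated genes were independent, with a replicate shift shared by all groups, so these shares may not hold for the real data.

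Among lists fixed before the data were examined, the cholesterol synthesis list fell, with 0 of 17 members higher and 17 lower, a median log2 change of -0.61 and a camera adjusted p of 3.08e-07. With an estimated correlation the adjusted p was 0.537. Its first members were Fdft1 (-1.21), the squalene synthase gene, and Fdps (-1.17). Germline genes fell as a list (1 higher, 17 lower, median -0.61, camera adjusted p of 1.21e-06, and adjusted p = 0.537 with an estimated correlation), led by Hormad2 (-3.12), a meiotic chromosome axis gene, and Tuba3a (-2.56). Adjusted over the list alone, 4 germline genes and 0 cholesterol genes passed, against 0 over all genes tested. Both lists kept their call without any 1 of the 6 libraries.

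Primitive endoderm markers rose as a list (8 higher, 2 lower, median 0.69, camera adjusted p of 0.00148, and adjusted p = 0.537 with an estimated correlation). Col4a2 (1.403), a basement membrane collagen, and Cited1 (-1.37) led it. Adjusted over the list alone, 6 members passed, the lower Cited1 among them, against 0 over all genes. Without Sall4 KO replicate 1 the list's camera adjusted p was 0.0985. Imprinted genes rose (10 higher, 5 lower, median 0.37, camera adjusted p of 0.0298, and adjusted p = 0.537 with an estimated correlation), with Peg3 and Igf2 (1.78), a growth factor gene, at the head. Over the list alone 6 passed, among them Nnat, which was lower. Without Sall4 het replicate 1 their camera adjusted p was 0.325 and without Sall4 KO replicate 2 it was 0.0995. The p53 targets rose (17 higher, 2 lower, median 0.30, camera adjusted p of 0.00148, and adjusted p = 0.537 with an estimated correlation), led by Perp (1.43) and Plk2 (0.79), with 1 member passing over the list alone. Without Sall4 het replicate 1 and without Sall4 KO replicate 1 their camera adjusted p was 0.438 and 0.123.

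Markers of primitive streak and mesoderm (5 higher, 1 lower, median 0.50, Nodal at 0.71 and Lefty1 at 0.67) had a camera adjusted p of 0.0433, and adjusted p = 0.537 with an estimated correlation. That call was lost without any 1 of the 6 libraries, with camera adjusted p of 0.198 and 0.0908 without Sall4 het replicates 1 and 2 and 0.0545 and 0.0995 without Sall4 KO replicates 1 and 2 and 0.0601 and 0.0685 without KO plus mutant replicates 1 and 2. Without Sall4 KO replicate 2 the Lefty1 value was -0.0276. Replication-dependent histone genes (3 higher, 15 lower, median -0.46, Hist4h4 at -1.39 and Hist1h3a at -1.34) had a camera adjusted p of 0.0433, and adjusted p = 0.780 with an estimated correlation of 0.71. Without Sall4 het replicate 1 and Sall4 KO replicate 2 it was 0.462 and 0.815, and in the latter fit the median was 0.0050 (9 higher, 9 lower). None of these camera calls, nor those of the mutant comparisons below, held with an estimated correlation. The fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 0 lists. Its mixed test, which asks whether they change in either direction and was read after the results were seen, called 9.

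The other 13 lists tested did not pass. Median log2 changes were 0.80 for the SALL family (camera adjusted p of 0.0536), 0.48 for fibroblast feeder markers (0.140), 0.26 for the NuRD complex (0.0978), 0.25 for primed epiblast (0.818), 0.19 for trophoblast (0.593), 0.17 for LIF and STAT3 targets (0.140), 0.098 for FGF and ERK feedback (0.140), 0.090 for cytosine methylation and oxidation (0.836) and 0.029 for naive and core pluripotency (0.799). They were -0.040 for neuroectoderm (0.799), -0.13 for WNT targets (0.394), -0.22 for glycolysis (0.147) and -0.33 for two-cell-like genes (0.108). The naive list had 12 members higher and 11 lower, with Tfcp2l1 at 1.20 beside Dppa3, and its mean and test were on the lower side. The means of primed epiblast and of cytosine methylation were also below 0, against their medians and tests, and there Otx2 was at -1.05, Sox4 at 0.94, Gadd45g at 0.98 and Gadd45a at -0.74. Id2 (1.55) and Phlda2 (-1.58) led the trophoblast list in opposite directions, as did Thy1 (-1.70) and S100a4 (1.502) among the feeder markers. Leaving out 1 library brought some of these lists under an adjusted p of 0.05 in camera. For the SALL family it was 0.00553 and 0.00102 without KO plus mutant replicates 1 and 2, for NuRD 0.0424 without KO plus mutant replicate 1, for feeder markers 0.0380 without KO plus mutant replicate 2, for FGF and ERK feedback 0.000779 without Sall4 het replicate 2 and 0.0250 without Sall4 KO replicate 2, and for glycolysis 0.00476 without Sall4 het replicate 2. For two-cell-like genes it was 4.17e-10 on the lower side without Sall4 het replicate 1, 0.0111 without Sall4 KO replicate 1 and 0.00151 on the higher side without Sall4 het replicate 2. The two-cell-like list differed between replicates, with a median log2 ratio of 0.96 in replicate 1 and -1.91 in replicate 2. In the fit on all 6 libraries its estimated correlation was 0.97, against the preset 0.01. Its members thus act nearly as 1 gene, and its small p-values above overstate the evidence. Only 1 of 35 Hox genes was measured above the filter, so that list was not tested. Adjusted over the list alone, 1 member each passed for naive pluripotency, trophoblast and feeder markers, which camera did not call. In the called primitive streak and histone lists 0 passed.

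**Figure D2:**
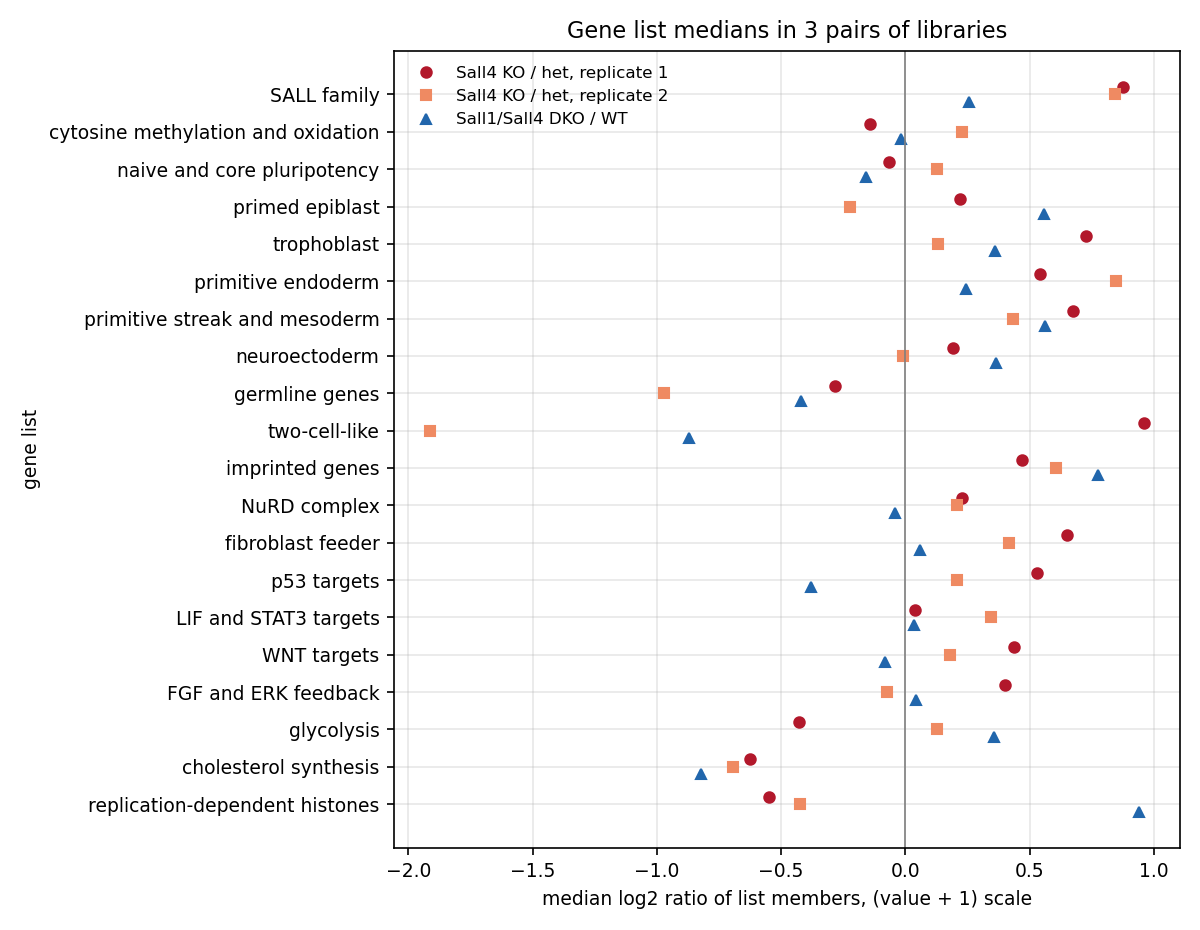
Median log2 ratio of the members of each gene list (horizontal axis, on the value plus 1 scale) in the pairs Sall4 KO over het of replicates 1 and 2 and DKO over its control, 1 symbol per pair with no error since each pair has 1 library per side. Cholesterol synthesis lies at -0.62, -0.69 and -0.82, while the two-cell-like list lies at 0.96, -1.91 and -0.87.

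The change seen in 1 replicate was partly seen in the other. Across 11465 genes, which are not independent replicates, the log2 ratio of KO to het in replicate 1 and in replicate 2 had a Pearson r of 0.223 and a Spearman rho of 0.301. Of 897 genes at 2-fold in replicate 1, 73.5% went the same way in replicate 2. Of 1492 genes at 2-fold in replicate 2, 68.3% went the same way in replicate 1. Over all genes the share was 59.8%. Both replicates had 140 genes at 2-fold higher, where independent lists would share 23.6, and 168 lower, where they would share 35.2. An excess over independent lists does not by itself show a shared change. DKO over its control and Sall1 KO over het had a Pearson r of only 0.046. They still shared 9 higher genes (2.47 for independent lists) and 19 lower (2.11). Both lines are labelled as lacking Sall1, so this pair cannot show whether such an excess arises without a shared change.

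Adding mutant SALL4A to the KO cells asks which of these RNAs move when a changed SALL4A is supplied. The libraries labelled KO plus mutant were compared with those labelled Sall4 KO. The comparison of KO with het used the same 2 KO libraries. Opposite directions in the 2 comparisons can therefore come from those libraries alone, and do not by themselves show a reversal by the mutant. Vim, the vimentin gene, was 68.3 and 37.9 against 484 and 265, a log2 change of -2.48 ± 0.26 (SE, n = 2 per group). Id2, an inhibitor of helix-loop-helix factors, was 6.78 and 7.60 against 49.1 and 41.2, a change of -2.20 ± 0.27. The log2 change of Sall4 was -1.01 ± 0.66, although these cells were given SALL4A, and without KO plus mutant replicate 1 it was 0.0216.

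The ranked higher genes were Pbld1 (3.54), the amino acid transporter gene Slc7a14 (3.23), Cyp2e1 (2.79), the chemokine receptor gene Cxcr2 (2.74), Lcmt2 (2.99), Ripply3 (2.92), Chrna1 (2.90), Ppp1r16b (2.70), Tapbpl (3.05) and Pilra (2.73). The ranked lower genes besides Vim and Id2 were Cryab (-2.54), Pmp22 (-2.34), the imprinted genes Nnat (-1.99) and Igf2 (-2.03), Cav1 (-2.32), Id1 (-2.38), Tagln (-2.13) and Anxa3 (-2.02). Limma called 0 of 11632 genes, with 1136 at an unadjusted p under 0.05 (599 higher, 537 lower) and a smallest adjusted p of 0.341. With values as deposited, where the median log2 change of all genes is -0.28, the split was 258 higher and 1620 lower. Without KO plus mutant replicate 1 it called 329 genes (326 higher, 3 lower), and without replicate 2 it called 787 (287 higher, 500 lower). Those sets shared 13 genes, of which 4 had the same sign. In each of these fits the lone mutant library is assumed to vary like the other groups.

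As lists, primitive endoderm markers fell (1 higher, 9 lower, median -0.64, camera adjusted p of 0.000498), as did fibroblast feeder markers (1 higher, 11 lower, median -0.88, 0.000949). With an estimated correlation the adjusted p was 0.550 for each, and both calls held without any 1 library. Dab2 (-1.57) and Sparc (-0.84) led the former, and Fbn1 (-2.60) and Tagln the latter. The growth protocol in the labels names no feeder cells. Adjusted over the list alone 2 and 4 members passed, against 0 over all genes. Imprinted genes fell (4 higher, 11 lower, median -0.31, camera adjusted p of 0.000722, adjusted p = 0.550 with an estimated correlation), with 7 passing over the list alone, and without KO plus mutant replicate 2 their adjusted p was 0.202. Cholesterol synthesis rose (16 higher, 1 lower, median 0.44, camera adjusted p of 0.000722, adjusted p = 0.550 with an estimated correlation), led by Insig1 (1.34) and Idi1 (1.11). As deposited, 10 were higher and 7 lower with a median of 0.14, and without KO plus mutant replicate 1 its adjusted p was 0.130.

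Germline genes rose (14 higher, 4 lower, median 0.49, camera adjusted p of 0.00176, adjusted p = 0.550 with an estimated correlation), led by Tuba3a (1.44) and Mael (0.98), with 1 passing over the list alone. As deposited their median was 0.25 (12 higher, 7 lower). Without Sall4 KO replicate 2 and KO plus mutant replicate 1 their adjusted p was 0.0809 and 0.235. Naive and core pluripotency genes rose (16 higher, 7 lower, median 0.23, camera adjusted p of 0.0237, adjusted p = 0.550 with an estimated correlation), led by Dppa3 (2.63) and Nanog (1.44). With values as deposited, 11 were higher and 12 lower with a median of -0.077, so the rise is relative to the other genes. Their adjusted p was 0.0744 and 0.0538 without Sall4 KO replicates 1 and 2 and 0.915 without KO plus mutant replicate 1. FGF and ERK feedback genes fell (4 higher, 11 lower, median -0.50, camera adjusted p of 0.0389, adjusted p = 0.662 with an estimated correlation), led by Fgfbp1 (-1.48) and Myc (-1.19). That call was lost without Sall4 KO replicate 1 (0.221) and KO plus mutant replicate 2 (0.643). Histone genes (2 higher, 16 lower, median -0.62) had a camera adjusted p of 0.0389 and adjusted p = 0.726 with an estimated correlation. Their medians were -1.74 in replicate 1 and 0.40 in replicate 2, with Hist1h1e at -1.04 and Hist2h3b at -1.03, and without KO plus mutant replicate 1 the median was 0.21 with an adjusted p of 0.148. The histone call was also lost without Sall4 KO replicate 1 (0.750) and Sall4 het replicates 1 and 2 (0.110 and 0.0510).

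The other 12 lists did not pass, with medians from -0.64 for the SALL family (camera adjusted p of 0.121) to 0.36 for two-cell-like genes (0.275). Two-cell-like genes had 0.0279 and 0.0282 without Sall4 het replicates 1 and 2, 0.0134 without Sall4 KO replicate 1 and 0.00977 without KO plus mutant replicate 2, all on the higher side, and LIF and STAT3 targets 0.0233 without the last. Without KO plus mutant replicate 1 the two-cell-like median was -0.66 (1 higher, 9 lower, adjusted p of 0.130), and without Sall4 KO replicate 2 it was -0.15. Median and test differed in sign for cytosine methylation and for glycolysis. Adjusted over the list alone, 2 trophoblast markers, 2 WNT targets and 1 cytosine methylation gene passed, in lists that camera did not call. In the called cholesterol, naive pluripotency, FGF and ERK feedback and histone lists 0 passed. The libraries differed in annotation as well as in cells, since the tables of KO and KO plus mutant list different gene sets. In replicate 1, 649 genes were at 2-fold higher and 1105 lower, while replicate 2 had 1633 higher and 222 lower. As deposited, these were 407 and 1630 in replicate 1 and 1332 and 511 in replicate 2. After scaling, the log2 ratios of the replicates over 8556 genes had a Pearson r of 0.130 and a Spearman rho of 0.258, and 59.1% of genes went the same way. Both replicates had 127 genes at 2-fold higher, where independent lists would share 27.2, and 80 lower, where they would share 21.4. As between the Sall4 KO replicates, this excess does not by itself show a shared change.

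Setting KO plus mutant against Sall4 het asks what still differs after the mutant is added. The het libraries are those set against KO above, so a direction seen in both comparisons can come from those libraries alone. Arhgap27 was 1.72 and 1.47 against 26.8 and 34.1, a log2 change of -3.39 ± 0.27 (SE, n = 2 per group), beside 2.28 and 1.64 in the KO libraries. The neuronal imprinted gene Nnat was at -3.12 ± 0.21, below both the het and the KO libraries. Also ranked lower were Lgals7 (-2.88), Eif2s3y (-3.47), Alox5ap (-3.38), Tnfrsf22 (-2.72), Id3 (-1.86), Hist1h4b (-2.03), Upp1 (-1.89) and Tmc5 (-2.80). Ranked higher were Cxcr2 (2.91), Nlrp1a (2.57), Slc7a14 (2.33), Trim43b (1.92), Cyp2e1 (1.71), D1Pas1 (1.73), Fxyd6 (1.63), Ppm1k (1.43), Kdelr3 (1.46) and the leptin receptor gene Lepr (1.74). Sall4 RNA differed by 0.26 ± 0.66. Limma called 0 of 11632 genes, with 1226 at an unadjusted p under 0.05 (566 higher, 660 lower, and 192 and 1595 as deposited) and a smallest adjusted p of 0.197. Without KO plus mutant replicate 1 it called 211 (202 higher, 9 lower) and without replicate 2 it called 677 (178 higher, 499 lower).

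Histone genes fell as a list in this comparison (2 higher, 16 lower, median -1.06, camera adjusted p of 0.00104, adjusted p = 0.874 with an estimated correlation). Their medians were -2.07 in replicate 1 and -0.054 in replicate 2, and the adjusted p was 0.322 without KO plus mutant replicate 1 and 0.0734 without Sall4 het replicate 1. WNT targets fell (1 higher, 7 lower, median -0.45, 0.0241), as did fibroblast feeder markers (2 higher, 10 lower, median -0.43, 0.0264), and p53 targets rose (12 higher, 7 lower, median 0.26, 0.0307), as camera adjusted p. With an estimated correlation the adjusted p was 0.874 for each, and 0 members of these lists passed adjusted over the list alone. In lists that camera did not call, 4 primitive endoderm members (Cited1, Col4a1, Col4a2 and Sparc) and 1 imprinted gene passed in that way. The WNT call was lost without KO plus mutant replicate 2 (0.295) and Sall4 het replicate 2 (0.0782). The feeder call was lost without KO plus mutant replicates 1 and 2 (0.0739 and 0.266) and Sall4 het replicate 2 (0.0636), and the p53 call without KO plus mutant replicates 1 and 2 (0.702 and 0.0806) and Sall4 het replicate 1 (0.837). The p53 median was -0.042 without Sall4 het replicate 1 (8 higher, 11 lower) and -0.0041 with values as deposited (9 higher, 10 lower). The other 16 lists did not pass. At the preset correlation of 0.01 several passed on leaving out 1 library, although the two-cell-like estimate was 0.97 in the full fit. Without Sall4 het replicate 1 these were primed epiblast (0.0199), neuroectoderm (0.0211), germline (0.000926), two-cell-like (3.02e-08, lower) and FGF and ERK feedback genes (0.0133). Without Sall4 het replicate 2 they were naive pluripotency (0.0433), two-cell-like (0.000166, higher) and glycolysis (0.0226). Without KO plus mutant replicate 1 they were germline and imprinted genes (0.0423 each) and two-cell-like and cholesterol genes (0.0277 each), and without its replicate 2 naive pluripotency (0.0303). Median and test differed in sign for cytosine methylation and primitive endoderm, and median and mean for LIF and STAT3 targets.

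The library labelled DKO was compared with its wild-type control to see which RNAs differ when both factors are targeted. There is 1 library on each side, so no value here has a replicate check. On the higher side the forkhead gene Foxd1 stood at a log2 ratio of 5.80, the NODAL inhibitor gene Lefty1 at 4.61 and the simple-epithelium keratin genes Krt18 and Krt8 at 3.78 and 3.51. Fgfbp1 (4.19), Dok2 (4.13), Gpx2 (3.94), Atp12a (3.60), Rtn1 (3.30) and the iron exporter gene Slc40a1 (3.28) completed the ranked set. On the lower side stood Rpl39l (-3.54), Cidea (-3.23), S100a13 (-3.22), the imprinted transporter gene Slc38a4 (-2.91), Serpinb6c (-2.88), the homeobox gene Hesx1 (-2.81), Accsl (-2.79), the meiotic kinase gene Aurkc (-2.77), Bhmt (-2.75) and LOC100861571 (-6.07). In all, 416 genes were at 2-fold higher and 316 lower of 8620 at a value of 5 or more. Sall4 RNA was higher in the library labelled DKO, against its label, and Sall1 RNA was lower.

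Set among 10000 random lists matched on level, 18 of 18 cholesterol synthesis genes were lower, with a median log2 ratio of -0.82 at percentile 0, led by Idi1 (-1.45) and Cyp51 (-1.15). The two-cell-like median was -0.87 (percentile 0, Zscan4b at -1.39 and Zscan4f at -1.03), that of germline genes -0.42 (0.07, Tuba3a at -2.13) and that of p53 targets -0.38 (0.05). Imprinted genes were at 0.78 (percentile 100), with Nnat at 2.75 beside Slc38a4, and histones at 0.94 (100), with 17 of 17 higher. Primed epiblast markers were at 0.56 (99.9, Zic2 at 3.03 and Lef1 at 2.88), primitive streak and mesoderm at 0.56 (99.4, with Lefty2 at 2.47), trophoblast at 0.36 (99.4), glycolysis at 0.36 (99.9) and neuroectoderm at 0.37 (97.3, Sox1 at 2.36). Of the methylation enzymes, Dnmt3l stood at 2.78 and Dnmt3b at 1.83, while the list's median was -0.019. Naive and core pluripotency genes had a median of -0.16 (8.36), with Utf1 at 1.46 and Tbx3 at -1.40. Against the mean ratio of Sall4 KO to het over 9235 genes, Pearson's r was 0.233 and Spearman's rho 0.260. These pairs share no library. They had 56 genes at 2-fold higher in both, where independent lists would share 9.68, and 71 lower, where they would share 10.3. As between the Sall4 KO replicates, such an excess does not by itself show a shared change.

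The library labelled Sall1 KO was compared with Sall1 het. Its Sall1 value of 13.3 was below the 21.8 of het, but near the 13.9 of the DKO control and above the 10.8 of TT2. The RNA therefore does not show that Sall1 is lost. A value for the whole gene that is not low can include parts that were not deleted, so it does not check this label. At 2-fold, 51 genes were higher and 59 lower of 8170, with 1 library per side, and 98 of these 110 carry names that the naming rule leaves out, mostly predicted genes and small RNAs. The named genes therefore reach below 2-fold. The higher side was led by the small nuclear RNA gene Rnu11 (2.51), Akr1b3 (1.57), Akap5 (1.51), the histone gene Hist1h4f (1.20), Rnu12 (1.18), Hist2h3b (1.17), Hist1h4h (1.13), Rmrp (1.02), Hist1h2bf (0.94) and Hist2h2aa2 (0.90). The lower side was led by LOC100861570 (-8.79), Lrrc17 (-2.09), LOC100861572 (-1.57), Insl3 (-0.98), Zscan4d (-0.87), Zscan4a (-0.83), the Y-linked gene Ddx3y (-0.75), Pts (-0.69) and Zscan4f (-0.69). All 8 measured two-cell-like genes were lower, with a median of -0.67 (percentile 0). The Zscan4 genes are near-identical copies that can share reads, so their single values are uncertain. Histones had a median of 0.38 (100). Medians nearer 0 but also beyond most random lists were 0.11 for primed epiblast (99.8), 0.11 for glycolysis (99.9), 0.093 for trophoblast (98.8) and -0.10 for feeder markers (0.235).

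Adding wild-type SALL4A to the KO cells was compared with Sall4 KO replicate 1, again with 1 library per side and with tables of different annotation. Dppa3 was higher at a log2 ratio of 5.23, together with H2-T23 (6.93), Tapbpl (5.12), Rpl39 (5.11), Lcmt2 (4.95), Ripply3 (4.76), Chrna1 (4.74), Pbld1 (4.65), the pigment gene Tyr (4.48) and Slc7a14 (4.43). The lower genes were Hist1h2ap (-8.62), Fyb (-7.20), Acads (-6.68), Cd59b (-6.22), Dennd1b (-6.10), Cnot6 (-6.04), Dynlt1f (-5.82), Gadl1 (-5.78), Adarb2 (-5.70) and Mob1b (-4.94). At 2-fold, 733 genes were higher and 1178 lower of 8399, that is 38.4% higher. With values as deposited, where the median log2 ratio is -0.25, the counts were 515 and 1590, that is 24.5% higher. Cholesterol synthesis genes had a median of 0.50 (percentile 99.9, Fdps at 2.13), germline genes 0.38 (98.2), fibroblast feeder markers -1.02 (0, Fbn1 at -4.87), histones -1.07 (0), primitive endoderm markers -0.73 (0.8, 0 higher and 11 lower), glycolysis genes -0.26 (1.39) and trophoblast markers -0.87 (0.02, Id2 at -2.32 and Hand1 at -2.27). Nanog stood at 2.94, while the naive and core pluripotency list had a median of 0.13 (percentile 46.6, 16 higher and 9 lower). Against Sall4 KO replicate 2, histones went the other way at 1.29 and trophoblast markers stood at 0.11, while cholesterol synthesis was at 0.73, germline genes at 0.81, feeder markers at -0.24 and the naive list at 0.027 (percentile 41.2). Primitive endoderm markers were at -0.73 there too (0.555, 0 higher and 9 lower), and two-cell-like genes were at 1.30 (100), against -0.11 (34.2) in replicate 1.

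The 2 add-back libraries whose tables share an annotation, KO plus wild type and KO plus mutant replicate 1, were compared after the data had been seen. At 2-fold, 175 genes were higher with the wild type and 101 lower of 8084, and 153 of these 276 carry names that the naming rule leaves out. The imprinted genes Nnat (3.81) and Mest (3.61), the interferon-response genes Isg15 (1.96) and Ifi35 (1.81), Dppa3 (1.84), Usp26 (1.71) and Xlr3a (1.62), Rpl26 (1.58) and Irak1 (1.503) were higher, after Rnu12 (4.64). Spink3 (-2.86), Trim52 (-2.001), Aoah (-1.71), Cnpy1 (-1.69), Zscan4b (-1.62), Raet1d (-1.61), Zscan4e (-1.60), Zscan4f (-1.57) and Mgmt (-1.53) were lower. The two-cell-like median was -1.10 (percentile 0) and the histone median 0.59 (100). Also lower were primitive streak and mesoderm at -0.44 (0.06), germline genes at -0.33 (0), primitive endoderm at -0.27 (1.03), p53 targets at -0.27 (0) and naive and core pluripotency at -0.16 (0.1), although Dppa3 was higher. WNT targets were at 0.22 (98.2) and primed epiblast at 0.18 (99.2).

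Genes chosen as 2-fold changed between KO and het in replicate 2 alone were then followed in replicate 1, in libraries not used to choose them, to see whether adding SALL4A moved them back. Of 628 genes higher in the library labelled KO, 417 were measured, and their median log2 ratio to Sall4 KO replicate 1 was -0.57 with wild-type SALL4A and -0.35 with the mutant (percentile 0 for each). Of 868 lower genes, 474 were measured, with medians of 0.28 and 0.17 (percentile 100 for each). At a level of 20 or more, the mutant median of lower genes was 0 (percentile 52.0), so it was not apart from random lists. Directly between the add-back libraries, the higher genes had a median of -0.13 and the lower genes 0.20 for wild type over mutant. For genes chosen at 4-fold the lower genes had a median of 0.26. The 49 higher genes had a median of 0, as did the random lists, so that value cannot show a difference. Both medians over KO share the same KO library, whose annotation differs from that of the add-back tables. Genes chosen in replicate 1 were also followed over Sall4 KO replicate 2. With the wild type the median was -0.73 over 245 higher genes and 0.65 over 294 lower genes. With the mutant it was -0.35 over 390 higher genes and 0.49 over 435 lower genes. The gene sets differ. The wild-type values are FPKM set against RPKM, while the mutant pair is RPKM on both sides. These medians therefore do not compare wild type with mutant. Genes chosen in DKO over its control gave -0.075 (percentile 2) and -0.13 for higher genes and 0.15 and 0.40 for lower genes. Wild type over mutant gave 0.0032 (percentile 94.1) for those higher genes and -0.13 for those lower genes, so neither kept the direction of genes chosen in replicate 2.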

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

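All tests of explanations in this part were chosen after the results had been seen.

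Dok2, an adaptor of tyrosine kinase signalling, was lower in the libraries labelled Sall4 KO than in het in both replicates, with log2 ratios of -1.45 and -1.78, and higher in the library labelled DKO than in its control, at 4.13. It stands out because the pairs moved in opposite directions. This difference was not tested, and the DKO library is also labelled as lacking Sall1.

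Sall4 RNA was higher in the libraries labelled Sall4 KO and DKO than in their controls. The smallest log2 ratio over these 3 pairs and 5 settings of scaling and pseudocount was 0.870, which argues against either as the whole cause. An exchange of the DKO and control labels would raise Sall1 in the library labelled DKO, and its log2 ratio was -2.17. Reads from a part of Sall4 that was not deleted remain open, because the table of Sall4 KO replicate 1 gives 1 entry for the gene and no value per exon. Whether loss of the protein raises its own RNA was not tested.

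Y-linked genes were low in the libraries labelled Sall4 KO and in the add-back libraries made from that line. The X-linked partner genes had a median log2 ratio of KO to het of 0.10 with a lowest value of -0.27, while the 4 Y-linked genes had a median of -1.60 and a highest value of -1.002. The gap between medians, 1.70, argues against scaling. A lower output of Y-linked genes after Sall4 loss stays open, since in the DKO over its control their median was 0.163, but that is 1 pair of libraries from another line. Loss of the Y chromosome in this line is a candidate explanation that also stays open. In all 5 libraries 4 of 4 genes were below both het values, but between KO and het the line and the Sall4 label cannot be told apart. The library labelled KO plus wild type is of the same line with wild-type SALL4A supplied, and there these genes were not restored. Eif2s3y was listed at 0, Ddx3y at 0.000163, Uty at 0.000309 and Ube1y1 at 0.273. That is 1 library, so it decides neither explanation. Wild-type TT2, whose annotation differs, was also below both het values for Ddx3y (0.811), Eif2s3y (5.18) and Uty (0.843), and does not list Ube1y1. It was above all 5 libraries for Ddx3y and Eif2s3y, but not for Uty. Of 2 further entries on this chromosome that some tables lack, AC154106.1 was 55.0 in Sall4 KO replicate 1 against 24.4 in het, but 25.1 against 58.6 in replicate 2. Gm3395 was 2.12 and 0.904 against 2.28 and 4.94. In KO plus mutant replicate 2 these entries were at 42.0 and 1.23.

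The two-cell-like list had opposite signs in the replicates of Sall4 KO over het. Under 5 settings of scaling and pseudocount the smallest gap between the replicate medians was 1.66, with opposite signs in each, which argues against those settings. Members other than Zscan4 had medians of 0.21 in replicate 1 and -1.37 in replicate 2, a gap of 1.58 that comes mainly from replicate 2. The fall in replicate 2 was thus not confined to the Zscan4 genes. For the rise in replicate 1, reads shared between the near-identical Zscan4 copies stay open. No biological explanation was tested.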

How the results depend on the processing

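Chosen after the data had been seen were the fit on genes present in all 6 tables, the list tests on het and KO libraries alone or without a mutant library, the genes chosen in replicate 1, the direct comparison of the add-back libraries, the mixed test of fry, the alternatives for the replicates of KO plus mutant and the limit of 1.5 times for an untested value; the other settings were planned. The cause of the moves below was not tested unless stated. Depth is unknown for these units and limits what low values can show.

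Limma called 0 genes between Sall4 KO and het under all settings except quantile normalization, which called 1, higher (Mir3060, named after its value was seen). For KO plus mutant against KO the count was 0 except on leaving out a library, where it ranged from 0 to 787. For KO plus mutant against het it was 0 except with a pseudocount of 0.1, which called 1, higher (Mir3060), and on leaving out a library, from 0 to 677. For Sall4 KO against het it stayed at 0 without each library in turn. A group left with 1 library is assumed to vary like the others.

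Same-numbered libraries deviated together with correlations of 0.578 for het and KO, 0.104 for het and KO plus mutant and 0.0632 for KO and KO plus mutant, so the numbers do not pair the samples by the rule set beforehand. With no replicate block, limma called 0 genes in each comparison (0 with it), with 890, 961 and 1029 at an unadjusted p under 0.05. Without the block, camera's adjusted p between Sall4 KO and het was 0.0846 for imprinted genes and 0.111 for histones, that of histones for KO plus mutant against KO 0.129, and that of feeder markers for KO plus mutant against het 0.0714, while the SALL family between Sall4 KO and het gained a call (0.0402).

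Lists called by camera fell from 7, 8 and 4 in the 3 comparisons to 0 in each with an estimated correlation and to 0 in each by fry's directional test. Fry's mixed test, for change in either direction, called 9, 6 and 4. Leaving out a library gave 4 (without het replicate 1) to 9 lists between Sall4 KO and het, 4 (without mutant replicate 1) to 8 for KO plus mutant against KO, and 2 (without mutant replicate 2) to 7 (without het replicate 1) for KO plus mutant against het. Over all lists and comparisons, leaving out a library ended a call in 36 values and made one in 28. With values as deposited the last comparison called 1 list, and its adjusted p was 0.0909 for WNT targets, 0.112 for feeder markers and 0.0909 for p53 targets. Histones for KO plus mutant against KO then had 0.236, and two-cell-like genes gained a call (0.0475). Values as deposited shift the median log2 change of all genes to -0.28 for KO plus mutant against KO and -0.24 against het.

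At 2-fold, DKO against its control gave 415 genes with a pseudocount of 5 and 360 at a level of 20, against 732, and KO plus wild type against KO gave 1258 and 1185, against 1911. Between the replicates of Sall4 KO over het, genes at 2-fold in both were 56 higher (5.67 for independent lists) and 74 lower (12.5) with a pseudocount of 5, and 68 (9.77) and 106 (24.1) at a level of 20, against 140 and 168. Between DKO and the mean Sall4 KO effect they were 21 (1.68) and 24 (2.30) with a pseudocount of 5, 32 (4.45) and 46 (5.93) at a level of 20, and 95 (17.4) and 113 (16.8) with a pseudocount of 0.1, against 56 and 71. In KO plus mutant against KO, a pseudocount of 5 gave 721 lower genes in replicate 1 and 113 in replicate 2, a level of 20 gave 635 lower in replicate 1 and 1063 higher and 111 lower in replicate 2, and values as deposited gave 407 higher in replicate 1 and 511 lower in replicate 2, against 649 and 1105 in replicate 1 and 1633 and 222 in replicate 2. Shared by both were then 66 higher (11.4) and 27 lower (4.65), 78 (24.0) and 34 (11.6), and 82 (11.3) and 197 (75.7), against 127 and 80, and the replicates' Pearson r was 0.0803 at a level of 20. The stricter settings keep fewer genes by construction. The medians that moved when SALL4A was added back were, for wild type, -0.0755 for higher and 0.15 for lower genes chosen in the DKO. For the mutant they were -0.13 for higher genes chosen in the DKO, and for lower genes 0 at a level of 20 (percentile 52.0, so not apart from random lists), 0.56 for genes chosen at 4-fold and 0.40 for those chosen in the DKO. As deposited, lower genes were at 0.0595 for wild type (95% of random lists from -0.26 to -0.11) and 0 for the mutant (-0.30 to -0.15), and higher genes at -0.58 for the mutant (-0.34 to -0.20). The random lists shifted as well, and each median stayed beyond them. For wild type over mutant the median of higher genes was 0 for those chosen at 4-fold, where random lists also gave 0, and genes chosen in the DKO reversed, at 0.0032 for higher and -0.13 for lower genes.

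Log2 changes of genes that reversed on leaving out a library are given as ranges. Between Sall4 KO and het they were -0.49 to 0.36 for Tet1, -0.11 to 0.28 for Tet2, -0.23 to 2.46 for Fgfbp1, -0.0276 to 1.37 for Lefty1 and -2.69 to 0.0313 for Pramel7. For KO plus mutant against KO they were -2.10 to 0.0216 for Sall4, -0.996 to 0.14 for Sall1, -0.0614 to 0.37 for Tet2, -2.43 to 0.18 for Dnmt3a, -0.67 to 3.27 for Gapdh, -1.53 to 0.15 for Gbx2, -2.16 to 0.0287 for Hist1h1e, -2.31 to 0.20 for Hist2h3b, -1.02 to 1.92 for Zscan4c and -0.80 to 1.49 for Zscan4d. For KO plus mutant against het they were -0.84 to 1.29 for Sall4, -0.20 to 0.94 for Sall1, -0.71 to 0.28 for Sall2, -3.29 to 0.30 for Fbn1, -0.72 to 3.22 for Gapdh, -0.0189 to 1.21 for Idi1, -1.10 to 0.17 for Nkd2 and -2.47 to 0.26 for Pramel7. With values as deposited, Tet2 for KO plus mutant against KO was -0.0906 and Sall4 for KO plus mutant against het was -0.0076.

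List medians that changed sign on leaving out a library ranged, between Sall4 KO and het, from -0.052 to 0.23 for cytosine methylation, -0.12 to 0.14 for naive pluripotency, -0.22 to 0.25 for primed epiblast, -0.26 to 0.21 for trophoblast, -0.15 to 0.056 for neuroectoderm, -2.20 to 1.01 for two-cell-like genes, -0.075 to 0.44 for LIF and STAT3 targets, -0.027 to 0.47 for FGF and ERK feedback, -0.46 to 0.20 for glycolysis and -1.24 to 0.0050 for histones. For KO plus mutant against KO they ranged from -0.15 to 0.021 for cytosine methylation, -0.66 to 1.26 for two-cell-like genes, -0.25 to 0.10 for p53 targets, -0.52 to 0.061 for LIF and STAT3 targets, -0.25 to 0.17 for glycolysis and -1.72 to 0.21 for histones. For KO plus mutant against het they ranged from -0.20 to 0.26 for the SALL family, -0.050 to 0.30 for cytosine methylation, -0.032 to 0.46 for naive pluripotency, -0.45 to 0.28 for primed epiblast, -0.18 to 0.23 for primitive endoderm, -0.57 to 0.038 for germline genes, -1.68 to 1.39 for two-cell-like genes, -0.32 to 0.032 for imprinted genes, -0.26 to 0.097 for the NuRD complex, -0.042 to 0.54 for p53 targets, -0.31 to 0.32 for LIF and STAT3 targets and -0.35 to 0.12 for FGF and ERK feedback. With values as deposited, medians that changed sign were 0.020 for WNT targets between Sall4 KO and het, -0.29 for cytosine methylation, -0.077 for naive pluripotency and -0.27 for glycolysis for KO plus mutant against KO, and -0.0076 for the SALL family, -0.070 for cytosine methylation, -0.22 for primitive endoderm, -0.035 for primitive streak, -0.0041 for p53 targets and -0.21 for LIF and STAT3 targets for KO plus mutant against het.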
